A study of Rattus norvegicus with 6 samples.

How the data were processed

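Individual-nucleotide resolution crosslinking and immunoprecipitation (iCLIP) was used to locate RNA sites bound by SYNCRIP in cytoplasmic RNA of rat cortical neurons kept for 6 days in vitro. SYNCRIP, also called hnRNP Q, is an RNA-binding protein of the heterogeneous nuclear ribonucleoprotein family. In iCLIP, ultraviolet light links proteins to the RNA they touch in living cells, an antibody recovers the protein with its RNA, and the sequenced ends of the recovered fragments mark the sites. Per the labels' protocols, cells grown on 10 cm plates were irradiated with UV-C at 300 mJ/cm2. The series has 6 samples in 2 groups, 3 precipitated with an antibody against SYNCRIP and 3 with an isotype-matched IgG. The submitters describe the 3 replicates of each group as biological. Peak lists of the 3 SYNCRIP libraries were used here, and the IgG libraries were not analysed here, so the background of the precipitation is not subtracted from, or set beside, any value in the report.

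STAR and the rat build rn6 are named in the submitters' processing notes, with no version of the aligner. The names of the deposited lists give the peak caller as Piranha with bins of 20 nt, and each library has a list of its own. The caller's version, its threshold, the treatment of duplicate reads and any use of the IgG libraries in calling are not given in the sources used here. The library barcodes in the labels hold random bases, which can be used to collapse PCR copies, and whether the authors collapsed them is likewise not given in the sources used here. Each deposited list gives chromosome, start, end, a whole-number score per peak and strand, with no header line. The lowest deposited score was 32, 26 and 20 in replicates 1, 2 and 3. No label says what the score counts or whether it was scaled. In the peaks wider than 1 bin, 79.3%, 79.6% and 81.0% of scores were below the list's lowest score multiplied by the number of bins, so the score of a wide peak is not a sum over bins that each reach that value. Scores were therefore used only to describe, rank or filter peaks within a list, and their values are not compared between lists. The remaining column of each list is 0 in every row, so no p-value of the caller was used. Sequencing depth is unknown, and list length is the only measure of yield.

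All peaks lie on a 20-nt grid. A single entry of replicate 1, on an unplaced Y contig, had its end before its start and no strand and was left out. Positions are given 1-based on rn6. No rn6 sequence or gene annotation was used here, and positions were not converted to another build, so peaks are named by position and not by gene. For the same reason the planned analyses of transcript location, position within the 3' UTR, 5-mers, target genes and the 13 gene lists fixed beforehand were not run.

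A peak was called shared when it overlapped a peak of another library by at least 1 bp on the same strand. Chance was measured by relocating each peak 1000 times on the grid within 10 kb of its own position, the fallback fixed before the data were examined for the case without an annotation. The one-sided p is the share of relocations, the observed value included, with at least as many shared peaks. Tested on simulated data made from replicate 1 (5687 peaks, 20 lists per setting), the excess over chance was estimated as 39.6% where 40.0% of peaks had been kept in place and as 79.6% where 80.0% had. Where none had been kept, the estimate was 0.173% and 4 of the 20 lists gave p under 0.05. The relocation p is therefore too small, and by how much in the real lists is not known. The simulated lists were made by the same relocation, which does not keep the spacing of real peaks. Peaks were therefore also moved by fixed distances of up to 500 nt, which keeps their spacing. Overlap rules were checked against a direct count on chromosome 12, with 0 differences over 80 peaks. Overlapping peaks of the 3 lists were merged into regions. Book-ended peaks of different lists were left apart, although the plan had merged them. A region with peaks of at least 2 libraries is called replicated and one with peaks of all 3 is called core. The rule for named genes, fixed beforehand, was applied to regions: the 20 core regions with the highest mean, over the 3 libraries, of the within-list percentile of their score. Clusters, chosen after the data were seen, are regions of one strand chained over gaps of at most 200 nt. The named clusters are those with at least 10 core regions.

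Shares of a single list carry 95% Wilson intervals, which cover counting error only and treat peaks as independent. Two-sided Fisher's exact tests compared core shares of mitochondrial and nuclear regions, and a permutation test with 1000 permutations compared clustered with isolated regions. Alternatives fixed beforehand were each replicate left out, a reciprocal overlap of 50%, a distance of up to 20 nt, strand ignored, all 3 libraries required and book-ended peaks merged. Alternatives added later were a score of at least 1.5 times the lowest of the list and lists cut to the 2733 highest-scoring peaks. Also added later were identical coordinates, relocation within 1 kb or 200 nt and lists without mitochondrial peaks. The last were mitochondrial regions outside their first plus-strand cluster and other chaining distances. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.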

Results

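The peak lists of 3 SYNCRIP iCLIP libraries from rat cortical neurons held 5687, 4163 and 2733 peaks in replicates 1, 2 and 3, a mean of 4194 ± 1477 (SD, n = 3). Most peaks were a single 20-nt bin wide (76.9% ± 1.5, SD, n = 3), and the widest reached 460, 380 and 340 nt. The median score was 45, 36 and 27 in the respective lists, and the highest 8374, 4693 and 2410. Nuclear peaks were divided evenly between the strands, with 49.8% (95% Wilson interval 48.5 to 51.1), 49.3% (47.7 to 50.8) and 51.0% (49.1 to 52.9) on the plus strand. No peak overlapped a peak on the opposite strand of the same list. Chromosome 1 held 8.86% ± 0.51 of the peaks, chromosome 2 held 8.35% ± 0.05 and chromosome 4 held 7.69% ± 0.16. Chromosome 6 held 6.48% ± 0.18, chromosome 3 held 6.38% ± 0.33 and chromosome X held 6.20% ± 0.63 (SD, n = 3 for each chromosome). The series also holds IgG libraries, which were not analysed here. The values below therefore describe where SYNCRIP libraries had peaks and how far the replicates shared them.

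The first question was whether the replicates placed peaks at the same sites. The 3 lists merged into 7023 regions, of which 3386 (48.2%) had peaks in at least 2 libraries and 1747 (24.9%) in all 3. Without replicate 1 the count of replicated regions was 1879 and without replicate 2 it was 2051. With only scores of at least 1.5 times the list's lowest it was 1433, with 727 core regions. Relocating every peak within 10 kb gave a mean of 266 replicated and 23.7 core regions and at most 308 and 39 in 1000 draws (p = 0.0010 for each, one-sided relocation permutation test, the smallest that 1000 draws can give). Without an annotation a relocated peak can leave its transcript, so libraries that merely share transcripts could exceed these counts. Region counts were not set against relocation over shorter distances. Of the core regions, which merge the peaks of all 3 lists, 697 (39.9%) were 1 bin wide. Replicates 1 and 2 alone had 1233 regions in common, replicates 1 and 3 alone 298, and replicates 2 and 3 alone 108. Replicate 1 had 2359 regions of its own, replicate 2 had 899 and replicate 3 had 379.

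**Figure D1:**
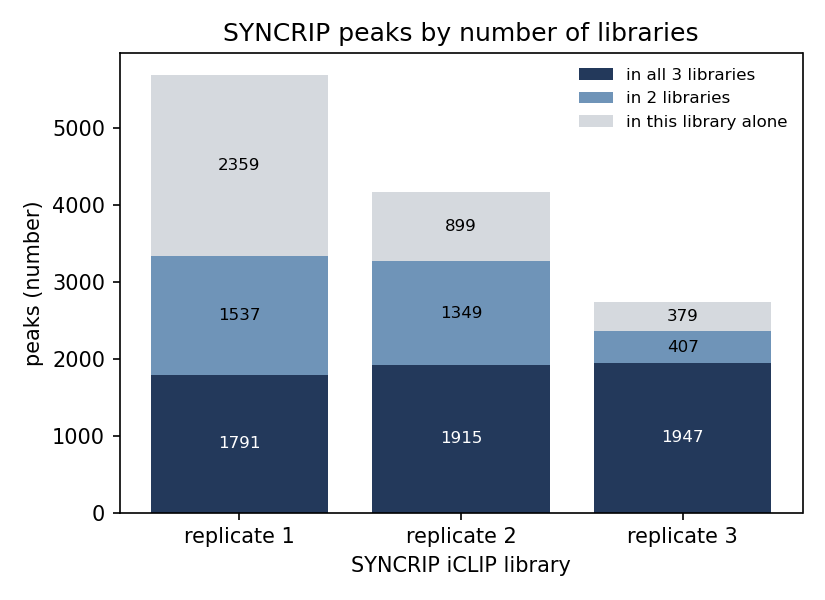
Number of peaks (y axis) in each SYNCRIP library (x axis), divided by the number of libraries in which their region was found. The dark segments, peaks in all 3 libraries, hold 1791, 1915 and 1947 peaks, and the pale segments, peaks of that library alone, hold 2359, 899 and 379.

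The share of one library's peaks that overlapped a peak of another was highest for the shortest list against the longest, and lowest the other way round. Of replicate 3 peaks, 81.4% (95% Wilson interval 79.9 to 82.9) overlapped a replicate 1 peak and 72.8% (71.1 to 74.4) a replicate 2 peak. Of replicate 2 peaks, 75.7% (74.4 to 77.0) overlapped replicate 1 and 45.7% (44.2 to 47.2) replicate 3. Of replicate 1 peaks, 53.2% (51.9 to 54.5) overlapped replicate 2 and 36.3% (35.0 to 37.5) replicate 3. Relocated peaks overlapped in 1.84% to 4.10% of cases, so that the observed shares were 19.7 to 22.0 times chance in the 6 ordered pairs (adjusted p = 0.0010 in each, relocation permutation test, Benjamini-Hochberg over the 6 pairs). The mean multiple was 21.0, and it fell to 5.16 with relocation within 1 kb and to 2.99 within 200 nt. With each list cut to its 2733 highest-scoring peaks, the shares ranged from 60.0% to 69.9%.

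The shared sites were local. Unmoved peaks overlapped in 60.9% of cases, the mean over the 6 ordered pairs. After all peaks of one list had been moved by 20 nt, the mean over both directions was 26.0%. It was 23.9% at 40 nt, 18.1% at 100 nt, 13.5% at 200 nt and 9.69% at 500 nt. In every pair the share at 40 nt was 0.37 to 0.42 of the share without a move. The shares at 200 and 500 nt were still above the 2.90% obtained by relocation within 10 kb. Peaks moved off their sites thus also exceed that chance, and the relocation p alone does not show shared sites. All these values take the lists as separate calls, which was not tested.

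**Figure D2:**
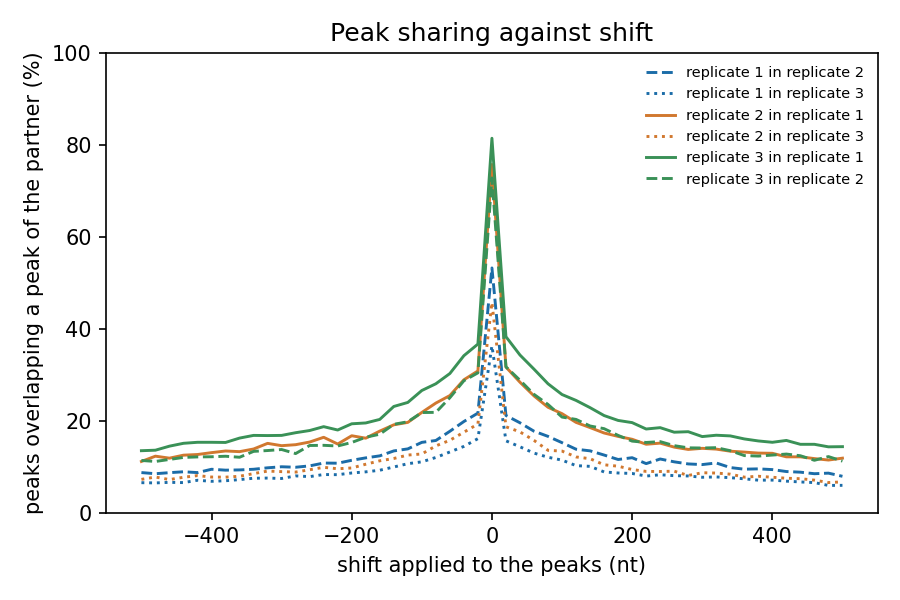
Share of a library's peaks that overlap a peak of a partner library (y axis, percent) after the peaks were moved by the distance on the x axis (nt), with 1 line per ordered pair of libraries (colour, the moved library; line style, the partner). Each line has its maximum at 0 nt, between 36.3% and 81.4%, and at a shift of 20 nt, averaged over both directions, the lines lie between 15.9% and 37.5%.

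Peaks without a partner were more frequent at low scores within their own list, but they were not confined to them. In the lowest decile of scores, 80.2% of replicate 1 peaks (95% Wilson interval 76.9 to 83.2), 51.8% of replicate 2 peaks (46.2 to 57.4) and 28.8% of replicate 3 peaks (23.6 to 34.6) had no partner in either other library. In the highest decile the numbers were 2 of 571, 0 of 414 and 1 of 274, or 0.350% (0.096 to 1.27), 0% (0 to 0.919) and 0.365% (0.064 to 2.04). In that highest decile, 93.2%, 96.9% and 97.8% of peaks lay in core regions. In decile 5, 47.7%, 20.9% and 14.1% of peaks in replicates 1, 2 and 3 still had no partner.

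**Figure D3:**
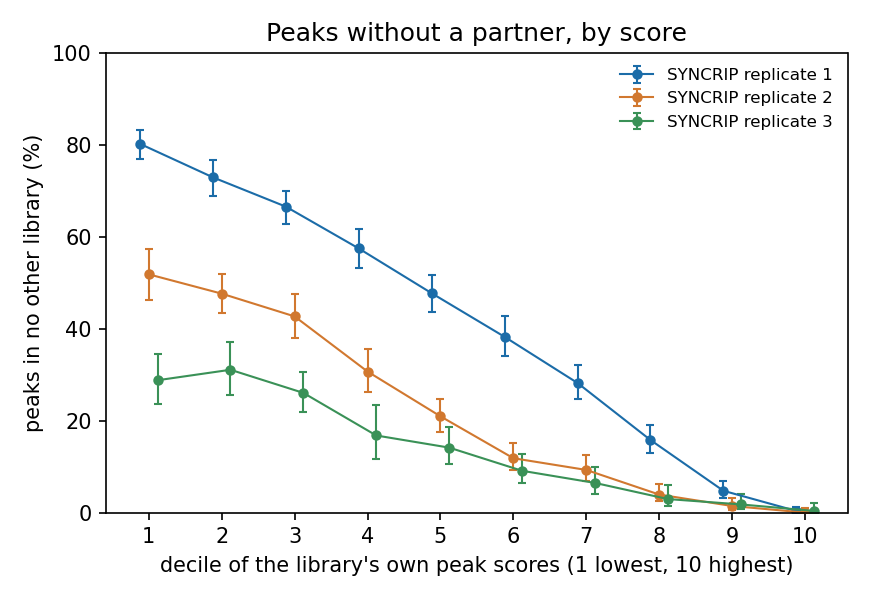
Share of peaks found in no other library (y axis, percent, with 95% Wilson intervals) against the decile of the library's own scores (x axis, 1 lowest to 10 highest), 1 line per SYNCRIP library. Replicate 1 falls from 80.2% to 0.350%, and all 3 libraries lie below 0.4% in the highest decile.

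The highest-ranking core regions were on chromosome 4 and on the mitochondrial chromosome. The first was a 100-nt region on the plus strand of chromosome 4 (77459781 to 77459880, rn6), the top-scoring peak in each list with scores of 8374, 4693 and 2410. The second lay 3160 nt downstream on the minus strand of chromosome 4 (77463041 to 77463100) and scored 2758, 1577 and 842. The next regions were both on the mitochondrial plus strand, at 281 to 380 with scores of 2558, 1903 and 829 and at 401 to 580 with scores of 745, 707 and 369. Chromosome 4 held another pair among the first 6. The minus-strand region at 100882241 to 100882280 scored 1867, 440 and 499, and the plus-strand region at 66276201 to 66276220 scored 1059, 756 and 247.

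The other ranked regions lay on 9 nuclear chromosomes and the mitochondrial chromosome. On chromosome 13, a plus-strand region at 91895901 to 91895920 scored 1268, 593 and 319 and a minus-strand region at 52263801 to 52263840 scored 465, 150 and 197. On chromosome 17, the minus-strand region at 85278041 to 85278060 scored 674, 350 and 157, and those on the plus strand at 43944341 to 43944360 and 44669501 to 44669520 scored 426, 235 and 146 and 263, 181 and 132. The region on the minus strand of chromosome 5 at 147634701 to 147634720 scored 798, 639 and 172, and that on the minus strand of chromosome 8 at 85480281 to 85480340 scored 603, 514 and 106. On chromosome 3, the plus-strand region at 154046041 to 154046140 scored 436, 209 and 163 and the minus-strand region at 102594821 to 102594840 scored 309, 151 and 121. The plus-strand region of chromosome 9 at 65291561 to 65291580 scored 355, 258 and 133. Another mitochondrial region at 1521 to 1700 scored 246, 221 and 150. The remaining regions were on chromosome 7 plus (99521361 to 99521400, with scores of 303, 177 and 128), chromosome 18 minus (65612001 to 65612020, with 342, 186 and 94) and chromosome 1 plus (266793421 to 266793460, with 338, 165 and 99). Of the 20 regions, 17 were nuclear and 9 were 1 bin wide. What the annotation places at these positions was not analysed here.

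Core regions lay in clusters along one strand. With regions chained over gaps of at most 200 nt, 1440 of the 1747 core regions (82.4%) lay in a cluster of at least 2 regions. Of all 7023 regions, 4979 (70.9%) did. Clustered regions also ranked higher in score, with a median percentile of 42.9 against 33.8 for isolated ones. The same contrast is compared within score quintiles under Other observations. Of the core regions, 838 (48.0%) lay in 1 of the 273 clusters of at least 5. The share of all regions in clusters of at least 5 was not computed, so 48.0% has no comparison. These larger clusters had a median span of 560 nt. With gaps of at most 100 nt or 1 kb instead, 76.1% or 89.2% of core regions lay in clusters of at least 2, against 63.1% or 82.7% of all regions. The share of core regions in clusters of at least 5 was then 35.1% or 68.9%, and their median span 400 or 1420 nt. The clusters named below use gaps of at most 200 nt. Their core counts were not set against relocation within the cluster, so overlaps that peak density alone would give are included. The cluster with the most core regions was on the minus strand of chromosome X (115098681 to 115105800), where 73 regions, 33 of them core, lay within 7120 nt, with 65, 64 and 64 peaks in replicates 1, 2 and 3. On the plus strand of chromosome 1 (264068861 to 264072400), 41 regions, 30 of them core, lay within 3540 nt, with 40, 38 and 40 peaks. On the plus strand of chromosome 9 (73459241 to 73462920), 39 regions, 25 of them core, lay within 3680 nt, with 35, 35 and 33 peaks.

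**Figure D4:**
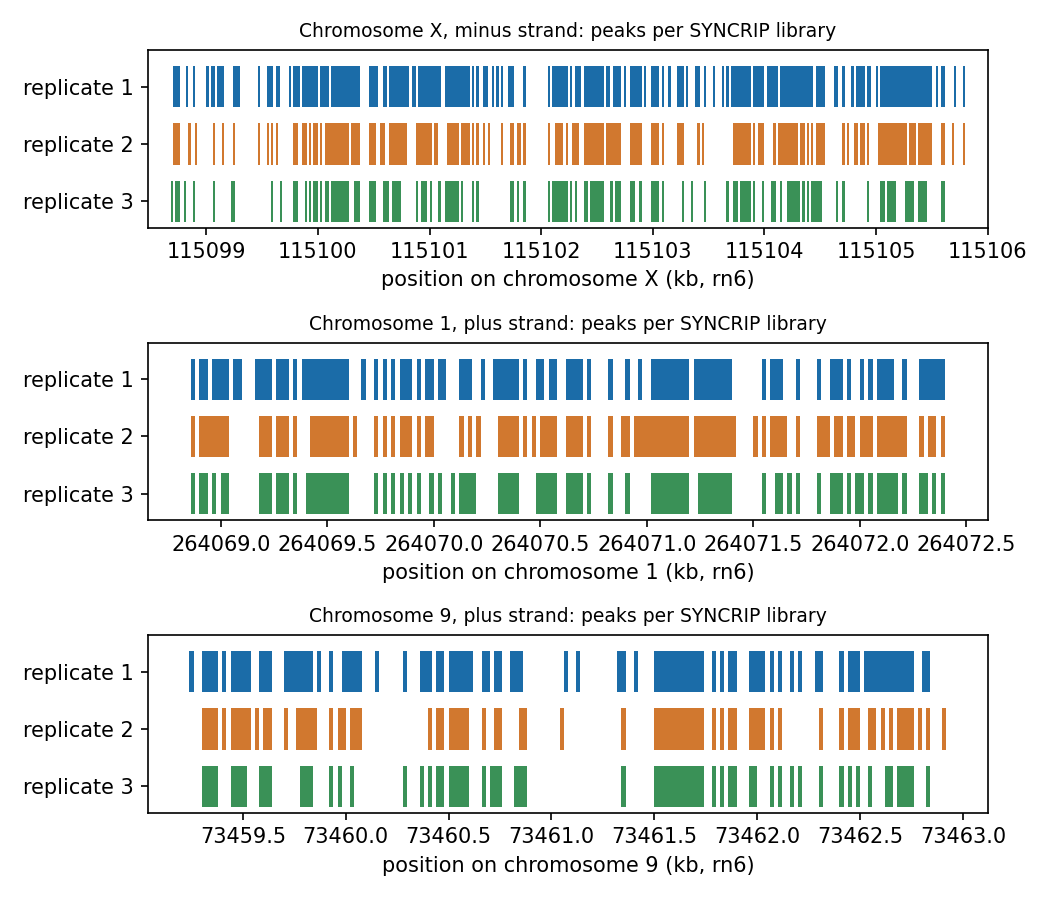
Peaks of the 3 SYNCRIP libraries (rows) along the nuclear clusters with the most core regions, on chromosome X minus, chromosome 1 plus and chromosome 9 plus (x axis, position in kb on rn6); each filled block is a peak, drawn to its width with no score. The clusters hold 33, 30 and 25 core regions, seen as blocks aligned across the rows.

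Smaller clusters followed on several chromosomes. The minus strand of chromosome 2 (29675461 to 29678440) had 17 core regions among 32, and the plus strand of chromosome 20 (42969121 to 42971680) had 13 among 30. The minus strands of chromosome 6 (46626421 to 46628000) and chromosome 18 (37713061 to 37714620) had 10 each, among 20 and 18 regions.

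Mitochondrial RNA gave 91, 84 and 74 peaks, or 1.60% (95% Wilson interval 1.31 to 1.96), 2.02% (1.63 to 2.49) and 2.71% (2.16 to 3.39) of the lists and 2.11% ± 0.56 on average (SD, n = 3). The mitochondrial genome encodes its own ribosomal and transfer RNAs and some subunits of the respiratory chain. The share was higher in replicate 3 than in replicate 1 by 1.11 percentage points (95% interval 0.45 to 1.85), a comparison of the lists with the highest and the lowest share whose interval covers counting error only and treats clustered peaks as independent. With each list cut to its 2733 highest-scoring peaks the difference was 0.622 percentage points and its interval included 0 (-0.19 to 1.45). With only scores of at least 1.5 times the list's lowest, which leaves lists of 2521 and 1073 peaks, it was 1.70 percentage points (0.54 to 3.10). Plus-strand peaks made up 93.4% (86.4 to 96.9), 97.6% (91.7 to 99.3) and 94.6% (86.9 to 97.9) of them. Of 115 mitochondrial regions, 47 were core (40.9%), against 1700 of 6908 nuclear regions (24.6%, two-sided Fisher's exact p = 0.00018, Benjamini-Hochberg adjusted p = 0.00036 over 2 tests across regions, which are not independent replicates). The stretch from 21 to 2660 on the plus strand held 27 regions, 21 of them core, which covered 79.5% of its length. Peaks of replicates 1, 2 and 3 covered 1840, 1800 and 1600 of its 2640 nt. Peaks that dense overlap often wherever they fall, so core status there says little about shared sites. The higher mitochondrial core share therefore does not show closer agreement of the libraries. The 88 mitochondrial regions outside this stretch were core in 26 cases (29.5%), a share whose difference from that of nuclear regions did not pass the test (two-sided Fisher's exact p = 0.32, adjusted p = 0.32). The stretch is the first plus-strand mitochondrial cluster and was chosen after the data were seen. Whether the remaining regions differ from nuclear ones is not settled by this test. No plus-strand peak lay between 9261 and 12080 in any of the 3 lists.

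**Figure D5:**
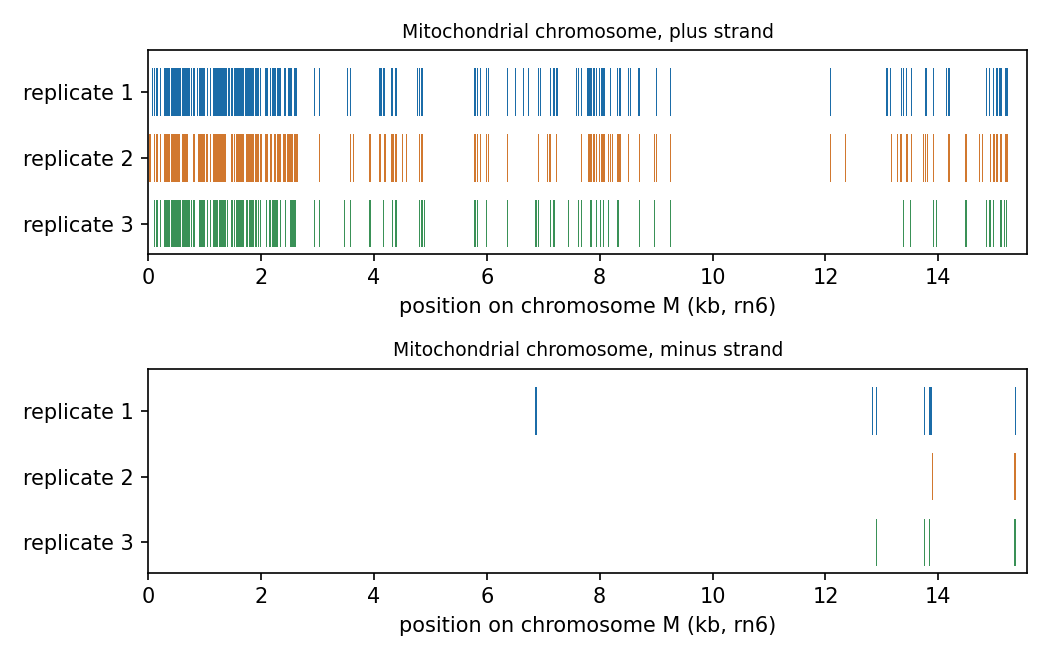
Mitochondrial peaks of the 3 SYNCRIP libraries (rows) by position (x axis, kb on rn6) on the plus strand (upper panel) and the minus strand (lower panel), drawn to their width with no score. Plus-strand peaks, 85, 82 and 70 in replicates 1, 2 and 3, cover 1840, 1800 and 1600 nt of the stretch from 21 to 2660. The minus strand has 6, 2 and 4 peaks.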

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

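Sharing between libraries stayed above chance in each ordered pair under each of the 12 alternatives run. Of these, 6 were fixed before the data were examined and the others chosen after. Those that left out a replicate only repeat ordered pairs of the main result, so they are no separate check of sharing. The mean shared percentage was 60.9% as reported and 52.7% with a reciprocal overlap of 50%, 70.0% with a distance of up to 20 nt, 60.9% with strand ignored, 60.7% without mitochondrial peaks, 64.5% at equal list length and 36.6% for identical coordinates. The multiple of chance fell from 21.0 to 5.16 with relocation within 1 kb and to 2.99 within 200 nt. Replicated regions numbered 3386 as reported and 1879 to 2984 with 1 replicate left out, which then requires both remaining libraries. The lowest value came without replicate 1, and 2051 remained without replicate 2. Requiring all 3 libraries gave 1747, and keeping only scores of at least 1.5 times the list's lowest gave 1433 replicated and 727 core regions and 1772 peaks per library, since fewer peaks enter. Identical coordinates gave 815 core regions. Merging book-ended peaks within a list left the peak counts unchanged, since no list held any. Book-ended peaks of different lists stayed in separate regions, a departure from the plan, and merging only those was not run. Joining peaks up to 20 nt apart, which includes book-ended ones, gave 2894 replicated and 1555 core regions. The mitochondrial share was 2.96% under the stricter score, against 2.11%; the cause was not tested. Sequencing depth is unknown and the lists differ in length, so a region missing from a list is not shown to be unbound in that library. No paired analysis was possible because the IgG libraries, which share the replicate numbers, were not analysed here. The stricter p-value of the caller, relocation over exons and the alternatives for transcript location, 3' UTR position, 5-mers, target genes and gene lists were not run, for lack of p-values in the lists and of an rn6 annotation.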

Other observations

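Regions with another region within 200 nt on their strand were core in 28.9% of cases (1440 of 4979), against 15.02% of isolated regions (307 of 2044), a difference of 13.9 percentage points. Their score ranked higher too, with a median percentile of 42.9 against 33.8. Within quintiles of the score percentile the difference was 8.26 percentage points (p = 0.0010, permutation within quintiles, the smallest that 1000 permutations can give). The permutation treats regions of the same cluster as independent, so its p may be too small. The difference within quintiles lies between the bounds set beforehand for and against score as the whole source of the difference, so whether score alone gives it stays open.

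The explanations that follow, and the comparison within quintiles, were tested against bounds written before the tested values were seen. The patterns themselves were noticed in these lists.

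Peaks of different libraries fell in the same bins far more often than at neighbouring bins. If the abundance of a transcript alone set the chance of a peak, at any position of a transcribed stretch, moving peaks by 40 nt would leave the sharing nearly as it was. The moved peaks kept 0.39 of the sharing, the mean over the 6 ordered pairs, with 0.37 to 0.42 in single pairs. If the lists are separate calls, this argues against abundance alone. The 815 peaks with identical coordinates stand first in each list, so the lists were handled jointly at some step before deposit. Whether that step raised the sharing of unmoved peaks was not tested. Positional preferences of another kind stay open, among them sites of SYNCRIP contact, the preference of UV crosslinking for certain bases, and positions that any precipitation would recover. The IgG libraries, which bear on the last of these, were not analysed here.

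Peaks seen in 1 library alone may be sites near the detection threshold rather than peaks peculiar to a library. The highest share without a partner in the top score decile of any library was 0.365%, against 28.8% to 80.2% in the lowest decile. A threshold would give this contrast. Low-scoring background calls peculiar to a library would give it too, so these values cannot tell missed sites from background. The IgG libraries, which bear on background, were not analysed here. If missed sites prevail, a large part of the 2359 regions found in replicate 1 alone would appear in the other libraries at greater depth. This was not tested.

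The higher mitochondrial share in the shorter list might follow from list length, if shorter lists keep mainly high-scoring peaks. With each list cut to 2733 peaks, the share in replicate 3 exceeded that in replicate 1 by 0.622 percentage points (95% interval -0.19 to 1.45), against 1.11 in the full lists. With only scores of at least 1.5 times the list's lowest it was 1.70 (0.54 to 3.10), in lists that again differ in length. The interval at equal length includes 0 and also the full-list difference, so that list length and a difference in mitochondrial RNA between the libraries cannot be told apart with this number of peaks.

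The 815 peaks with identical coordinates in all 3 libraries stand first in each deposited list, in the same order. The order of the rest of the lists was not used here. Because this order depends on the other lists, the lists were handled jointly at some step before deposit. Whether that step changed which peaks a list holds is not given in the sources used here. The sharing values, and the argument drawn from moved peaks, take the lists as separate calls, and this was not tested.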
